A study of Arabidopsis thaliana with 8 samples.

How the data were processed

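RNA was measured by sequencing in 8 libraries of Arabidopsis rosette leaves, 2 for each of 4 genotypes. The labels give the tissue as rosette leaf while the series text speaks of seedlings. The series text calls the libraries biological replicates. The labels do not say that a replicate number marks a shared day or batch.

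The deposited values are whole-number counts per gene, not normalized, in a table of 34262 genes for the whole series. Per the submitters' processing notes, the tools included bcl2fastq 2.17.1.14, HISAT2 2.1.0, SAMtools 1.5, HTSeq 0.9.1 and a DESeq2 version given as 3.9, with the TAIR10 genome build. RNA was extracted with Trizol, per the labels' protocols. Whether counting used strand is not given in the sources used here. A column whose name lacks a digit of gbpl1-1 was taken as gbpl1-1 replicate 1, since its name matched no other sample. The table also holds 5 lines that name no gene, and these stayed out of library sizes and tests. They took 22.5 to 28.8% of all reads, of which reads without a unique alignment made 8.02 to 14.5%, ambiguous reads 5.61 to 6.44%, low-quality alignments 4.08 to 4.55%, reads outside features 2.07 to 3.35% and reads not aligned 1.61 to 1.74%. Leaving out reads without a unique alignment lowers the counts of genes with near-identical copies.

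Gene counts per library were 15390261 and 16067538 in wild type, 20404271 and 15756783 in gbpl1-1, 18313788 and 22173943 in gbpl3-5, and 22632851 and 25763193 in GBPL3-OX. Chloroplast genes took 56.3 to 64.0% of them, and the chloroplast gene psbA alone 36.9 to 42.4%, so the precision for nuclear genes rests on 5473451 to 11030612 counts. The 10 most abundant nuclear genes took 15.0 to 15.5% of nuclear counts in wild type and gbpl3-5 and 5.60 to 6.18% in gbpl1-1 and GBPL3-OX. A gene at 0 counts was given a floor of 3 counts per library, and folds against it are lower bounds. Counting intervals are exact at 95%, and they and the floors cover counting error only.

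Genes were named from the TAIR10.1 RefSeq annotation, in which 32548 identifiers matched. Of the rest, 285 are organelle genes and 1429 carry an ENSRNA identifier. The table carries no coordinates, so those printed are from TAIR10.1, on the minus or plus strand as annotated.

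Counts were analysed in R 4.3.3 with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest), with TMM scaling (factors from 0.843 to 1.205). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17602 and removed 16660. All 8 libraries entered a single fit with genotype as the only term, so that the 4 groups share an estimate of the spread (common biological coefficient of variation 8.70%). Adjusted p-values are Benjamini-Hochberg values, two-sided, from edgeR's quasi-likelihood test unless another tool is named, with a threshold of 0.05. Each group has n = 2. Expression is given as CPM, counts relative to the TMM-scaled library size, with the SD over 2 libraries, and log2 fold changes with their standard error. Each line was compared with wild type, and the 3 lines with each other.

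The 22 gene lists were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. No member's identifier contradicted the annotation. Of the lists 20 had at least 2 tested genes. They were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation and with fry, adjusted over all lists and the 3 comparisons. Among these 60 tests camera called 29, and none of the 29 held with an estimated correlation. Fry, which does not compare a list with other genes, called 39 of the 60. Lists overlap in 3 genes. The wound and touch, root, flower, stomatal and phloem lists serve as markers of handling and of other tissues.

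Named genes followed a rule with 4 parts. Part (a) took GBPL1 and GBPL3, and part (b) PR1, PR2, PR5, ICS1, EDS1, PAD4, SARD1, CBP60G, FMO1 and ALD1, whatever their result. Part (c) took up to 4 called members of each list, smallest p first, which gave 79 genes in gbpl1-1 and 79 in GBPL3-OX. Only examples of these are named. Part (d) took the 8 largest folds each way among called genes with a mean log2 CPM of at least 1 whose libraries did not overlap those of the other group, or 4 each way between lines. Others are named as chosen after their values were seen.

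The same steps were tested on simulated data. Counts for 17602 genes in all 8 libraries were drawn from group means and library sizes, in 5 simulations. The gbpl3-5 libraries took the wild type means, with 200 genes changed. Changes of 0.5, 1, 2 and 3 on the log2 scale were recovered in 25.6, 76.4, 90.0 and 95.2% of cases, and 7.24% of calls were false. The changed genes were picked among those averaging above about 1 CPM, so these rates do not cover weaker tested genes. To gauge shared controls, all 8 libraries were drawn anew 20 times from the wild type means, with no gene changed.

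Alternatives were DESeq2 size factors or library size alone in edgeR, no low-count filter, a stricter filter (at least 1 CPM in 2 libraries and a mean of 10 counts), leaving out organelle genes, the replicate number as a block, DESeq2 1.42.0, limma-voom, a fit of only the 4 libraries compared, and leaving out each library in turn. After the data were seen, 3 additions were made: a contrast that crosses the genotypes, pairs of comparisons that share no library, and 10 gene families taken from names and products in the annotation, leaving out genes whose symbol resembles a family's but whose product is another.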

Results

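The data were RNA sequencing counts per gene from rosette leaves of Arabidopsis thaliana, grown for 3 weeks in 12 h of light and 12 h of dark, harvested at 10:00 and given no treatment. The 8 libraries came from 4 genotypes with 2 libraries each. They were the Col-0 wild type, the gbpl1-1 and gbpl3-5 lines, and a line named GBPL3-OX. GBPL1 and GBPL3 are annotated as guanylate-binding family proteins, and the series title names a circuit of such proteins in immunity as its subject. Gene counts per library ran from 15390261 to 25763193, of which chloroplast genes took 56.3 to 64.0% and nuclear genes 5473451 to 11030612 counts. Of 34262 genes, 17602 had enough counts to be tested. The libraries fell into 2 sets. Across genes, log2 CPM values correlated at 0.982 to 0.993 between libraries of the same genotype, at 0.983 to 0.985 between wild type and gbpl3-5, and at 0.985 to 0.990 between gbpl1-1 and GBPL3-OX, but at 0.541 to 0.611 across these sets. Genes are not independent replicates, so these correlations describe the libraries only.

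The targeted genes were examined first, as a check of the labels. GBPL1 (AT1G03830, chromosome 1, 961684 to 966790 on the minus strand of TAIR10.1) was weakly expressed in wild type, at 0.885 ± 0.0523 CPM (SD, n = 2, 11 and 13 counts). It fell by 2.29 on the log2 scale in the libraries labelled gbpl1-1, to 0.169 ± 0.0688 CPM (SE 0.58, edgeR adjusted p = 0.00196). It also fell by 3.27 in the libraries labelled GBPL3-OX, to 0.0875 ± 0.0319 CPM (SE 0.61, edgeR adjusted p = 0.000126). In the libraries labelled gbpl3-5 it stood at 0.220 ± 0.0498 CPM, a log2 fold change of -1.96 (SE 0.57) that did not pass the test over all genes (edgeR adjusted p = 0.689). GBPL1 was therefore low in each of the 3 lines, on 2 to 5 counts per library, and did not set gbpl1-1 apart from gbpl3-5 (log2 fold change -0.33, edgeR adjusted p = 0.699) or from GBPL3-OX (0.98, edgeR adjusted p = 0.947).

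GBPL3 (AT5G46070, chromosome 5, 18683319 to 18688822 on the plus strand) was not higher in the libraries labelled GBPL3-OX. It averaged 10.7 ± 1.04 CPM there and 10.6 ± 2.93 in wild type (n = 2 each), a log2 fold change of 0.01 with a 95% interval from -0.35 to 0.37 (edgeR adjusted p = 0.950). Scaled by library size alone the value was 0.49 (edgeR adjusted p = 0.0250), where the median of all genes stood at 0.43. In the libraries labelled gbpl3-5 GBPL3 averaged 12.1 ± 1.48 CPM (log2 fold change 0.18, SE 0.17, edgeR adjusted p = 0.971), and in those labelled gbpl1-1 8.95 ± 0.755 CPM (-0.24, SE 0.18, edgeR adjusted p = 0.233). Without wild type replicate 1 the value for gbpl1-1 was -0.48 and passed the test (edgeR adjusted p = 0.0279). GBPL3 was lower in gbpl1-1 than in gbpl3-5 by a log2 fold change of -0.42 (95% interval -0.78 to -0.06, edgeR adjusted p = 0.0337). The transcript counts thus went against the GBPL3-OX label, and did not set gbpl3-5 apart from wild type. Genotype names below are the labels of the libraries, and directions given for GBPL3-OX are for the libraries labelled so. The paralog GBPL2 ran from 8.57 CPM in wild type to 10.2 in gbpl1-1 and passed the test in none of the 3 lines.

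**Figure D1:**
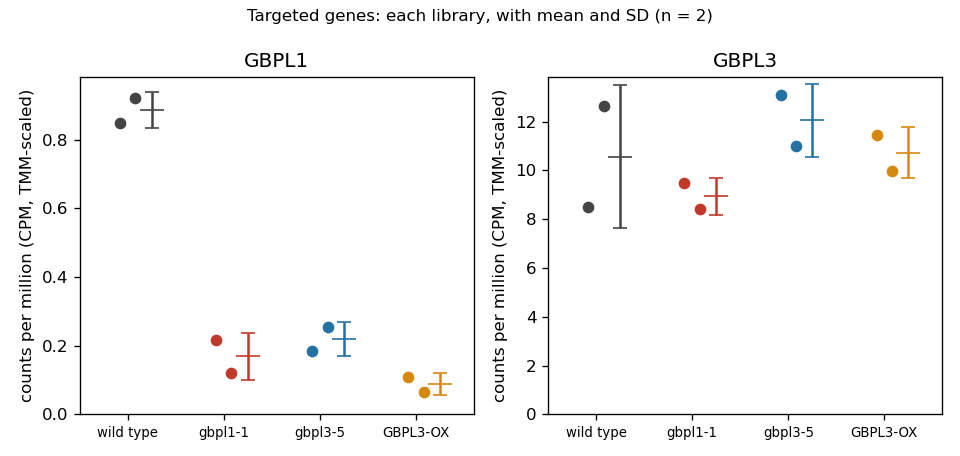
GBPL1 (left) and GBPL3 (right) in CPM with TMM scaling, with a point for each library of the 4 genotypes and the mean with its SD beside them (n = 2). GBPL1 was highest in wild type, at 0.885 CPM on average, while GBPL3 lay at 10.7 CPM in GBPL3-OX and 10.6 in wild type.

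The comparison of gbpl1-1 with wild type asked what changes in an unchallenged leaf of that line. Defence genes were strongly expressed in gbpl1-1 and photosynthesis and growth genes were low. PR1, the classic marker of salicylic acid signalling, rose from 4.64 ± 0.458 CPM to 3296 ± 232 (SD, n = 2), a log2 fold change of 9.47 (SE 0.21, edgeR adjusted p = 8.77e-15). PR2 and PR5 rose by 5.04 and 5.57 on the log2 scale. ICS1, the enzyme that starts salicylic acid synthesis from isochorismate, rose by 4.67, from 10.6 ± 0.104 to 271 ± 1.1 CPM. SARD1 and CBP60G, transcription factors that act on ICS1, rose by 5.15 and 6.08, and EDS1 and PAD4, which act upstream of salicylic acid, by 2.45 and 3.53. ALD1 and FMO1, which make the systemic resistance signals pipecolic acid and N-hydroxypipecolic acid, rose by 10.26 and 9.67, ALD1 from 0.480 ± 0.0239 to 597 ± 163 CPM. The edgeR adjusted p of these 10 genes was at most 2.39e-05.

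Of the 31 tested genes of the salicylic acid and systemic resistance list, 29 rose and 1 fell (30 and 1 adjusted over the list alone), with a median log2 fold change of 4.69. The camera test called the list (adjusted p = 5.18e-11), but not with the correlation between its genes estimated from these libraries (adjusted p = 0.0819 with an estimated correlation). Among pattern-triggered immunity genes 23 of 26 rose and 1 fell, with a median of 3.10 (camera adjusted p = 2.51e-07; adjusted p = 0.0819 with an estimated correlation). FRK1, a receptor kinase induced by flagellin, rose by 8.15 and WRKY33 by 4.32, while FLS2, the flagellin receptor, stood at 0.00 and was not called. Of 26 genes listed as intracellular immune receptors 23 rose and 1 fell, with a median of 1.08 (camera adjusted p = 1.56e-05, and adjusted p = 0.0819 with an estimated correlation). ADR1 rose by 2.80. Of 34 cysteine-rich receptor-like kinases 25 rose, among them CRK7 by 7.81 and CRK36 by 7.46, and 5 fell (camera adjusted p = 7.50e-05; adjusted p = 0.0874 with an estimated correlation). Their median was 2.65, or 2.61 with the gene at 0 counts set at its bound.

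Secondary defence metabolism split in gbpl1-1. Of 20 camalexin and indole glucosinolate genes 17 rose and 2 fell, with a median of 3.37 (camera adjusted p = 4.59e-06; adjusted p = 0.138 with an estimated correlation). CYP79B2, which commits tryptophan to indolic compounds, rose by 5.60. Of 18 aliphatic glucosinolate genes 17 fell and 0 rose, with a median of -4.48 (camera adjusted p = 6.87e-05; adjusted p = 0.554 with an estimated correlation). MYB29, a regulator of that pathway, fell by 5.75 (-7.70 without gbpl1-1 replicate 1 and -5.10 without replicate 2), and the sulfotransferase SOT18 by 2.59. Glutathione transferases, which conjugate reactive compounds, rose in 16 of 17 cases and fell in 1, with a median of 6.77 with the gene at 0 counts set at its bound and 6.83 as fitted (camera adjusted p = 4.42e-06; adjusted p = 0.201 with an estimated correlation). GSTF2 rose by 6.73 and GSTU10 by 6.77. GSTF6 rose by 7.72 and GSTF7 by 7.96, but these are close paralogs whose reads can be shared, so their separate values are uncertain.

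Jasmonate and ethylene defence genes moved the same way as those of salicylic acid. Of 29 genes 25 rose and 3 fell, with a median of 3.01 (camera adjusted p = 3.95e-06; adjusted p = 0.210 with an estimated correlation). TAT3 rose by 8.11, from 10.3 ± 0.712 to 2841 ± 368 CPM, and the lipoxygenase gene LOX4 by 5.07. Protein folding genes of the endoplasmic reticulum rose in 18 of 18 cases, with a median of 2.79 (camera adjusted p = 1.19e-07; adjusted p = 0.156 with an estimated correlation), among them the chaperone BIP2 by 3.81 and PDIL1-2 by 4.16. Heat shock genes rose in 15 of 16 cases and fell in 0, HSP90.1 by 5.82 and HSP70-4 by 4.34, with a median of 2.52 with the gene at 0 counts at its bound and 2.98 as fitted (camera adjusted p = 8.54e-05; adjusted p = 0.255 with an estimated correlation). All 14 tested leaf senescence genes rose, SAG13 by 8.88 and WRKY6 by 4.87, with a median of 4.04 with the gene at 0 counts at its bound and 5.42 as fitted (camera adjusted p = 3.81e-06; adjusted p = 0.169 with an estimated correlation). Genes that respond within minutes to wounding and touch rose in 16 of 20 cases and fell in 2, WRKY40 by 6.49 and CML12 by 4.99, with a median of 3.64 (camera adjusted p = 0.000101; adjusted p = 0.0858 with an estimated correlation).

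Photosynthesis genes of the nucleus fell in 45 of 45 cases, with a median of -3.55 (camera adjusted p = 6.92e-13; adjusted p = 0.480 with an estimated correlation). PSAE1, a photosystem I subunit, fell by 2.98, from 532 ± 12.9 to 67.3 ± 7.54 CPM. LHCB2.3 fell by 8.30, from 1400 ± 28.3 to 4.43 ± 0.0656 CPM, and LHCB1.3 by 4.08, although light-harvesting genes have near-identical copies that can share reads. Cell wall expansion genes fell in 14 of 15 cases and rose in 1, with a median of -5.72 (camera adjusted p = 9.33e-05; adjusted p = 0.0866 with an estimated correlation), EXPA1 by 4.87 and EXPA8 by 8.11 (-10.06 without gbpl1-1 replicate 1 and -7.47 without replicate 2).

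The other lists fixed before the data were examined were not called by camera in gbpl1-1. Of 25 abscisic acid and cold genes 14 fell, such as COR15A by 4.96 and RD22 by 5.08, and 8 rose, such as RD26 by 3.47 (median -0.94, camera adjusted p = 0.267). Of 15 clock genes 8 fell, COL2 by 5.81 and CCA1 by 1.26, and 1 rose (median -0.87, camera adjusted p = 0.129). Of 7 anthocyanin genes 4 fell, CHI by 4.09, and 2 rose, the regulator PAP1 by 3.55 (median -0.69, mean -0.51, camera adjusted p = 0.648). Of 16 nuclear lamina, nuclear basket and Mediator genes 6 rose, MED16 by 1.72, and 3 fell, with CRWN2 at -2.14 (median 0.20, camera adjusted p = 0.321). Of 6 stomatal and guard cell markers 3 fell, GC1 by 3.25, and 1 rose, KAT1 by 1.03 (median -1.65, camera adjusted p = 0.321). Of 7 phloem markers 2 rose, SWEET12 by 4.70, and 3 fell, SEOR1 by 1.65. Their median was -0.28 and their mean 0.37, and the median turned to 0.07 with library size scaling (camera adjusted p = 0.911). For the lists other than salicylic acid, the counts adjusted over the list alone were those given above. Without gbpl1-1 replicate 1 COL2 stood at -6.54, CHI at -5.32 and GC1 at -4.41. None of the 11 root markers had enough counts to be tested (at most 10 counts in a library), and of 16 flower, seed and shoot meristem markers only AG was tested, which averaged 0.628 ± 0.0152 CPM in wild type and fell by 2.25 (edgeR adjusted p = 0.0118). The value for AG was -1.36 without gbpl1-1 replicate 1 (0.156), -3.66 without gbpl1-1 replicate 2 (0.00438), -2.22 without wild type replicate 2 (0.0549) and -2.17 by DESeq2 (adjusted p = 0.0726).

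Several genes went from 0 counts to well above 10 CPM in gbpl1-1. Against 0 counts in both wild type libraries, and with 3 counts per library as the floor, the glutamate receptor gene ATGLR1.2 was at least 221-fold higher, GSTL1 at least 169-fold, AT1G76470 at least 169-fold, AT1G33030 at least 115-fold, the wall-associated kinase gene WAKL10 at least 112-fold, GLYI7 at least 99.4-fold and AT1G57650 at least 88.6-fold. BSMT1, a methyltransferase that makes methyl salicylate, was at least 93.4-fold higher, and its call was lost without gbpl1-1 replicate 1 or replicate 2 (edgeR adjusted p = 0.0600 and 0.0697), with fitted log2 fold changes of 12.05 and 11.23 against 11.68 in all libraries, which are no bounds at 0 counts. In the other direction, 0 counts in gbpl1-1 made the thionin gene THI2.2 at least 74.7-fold lower, the plasmodesmal gene PDLP3 at least 70.6-fold, AT5G05890 at least 67.5-fold, the expansin gene EXPA3 at least 64.2-fold, AT2G38995 at least 50.9-fold, the pectate lyase gene AT1G67750 at least 49.6-fold, AT2G02780 at least 44.6-fold and KCS8 at least 42.9-fold. Over all tested genes, 6535 were higher and 6757 lower in gbpl1-1 by edgeR, 4393 and 5203 of them by at least 2-fold. With so many genes changed the centre of the fold changes depends on the scaling: with library size alone the median of all genes was 0.30, against -0.04 with TMM.

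**Figure D2:**
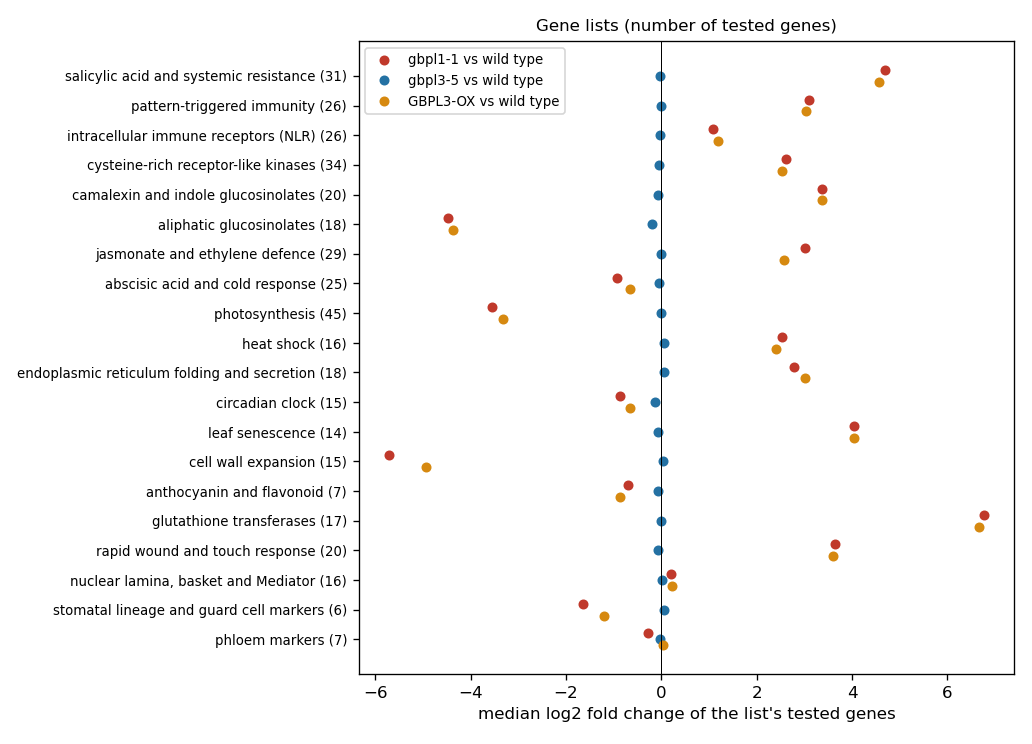
Median log2 fold change against wild type (x axis) of the tested genes of each of 20 gene lists (y axis, number of tested genes in brackets) for gbpl1-1, gbpl3-5 and GBPL3-OX, with genes at 0 counts in a group set at their bound. The salicylic acid list lay at 4.69 in gbpl1-1, 4.57 in GBPL3-OX and -0.02 in gbpl3-5. With library size scaling the median turned for the phloem list of gbpl1-1, to 0.07, and for 6 lists of gbpl3-5 that lay near 0. That scaling also moved the median of all genes, to 0.30 in gbpl1-1 and 0.06 in gbpl3-5. Relative to all genes the phloem list of gbpl1-1 stayed at -0.23.

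The comparison of GBPL3-OX with wild type gave the same picture of high defence and low photosynthesis, in libraries whose GBPL3 counts did not differ from wild type. PR1 rose by 9.34 on the log2 scale, from 4.64 ± 0.458 to 3021 ± 173 CPM (SD, n = 2, SE 0.21, edgeR adjusted p = 5.78e-15). PR2 rose by 5.15, PR5 by 5.50, ICS1 by 4.57, EDS1 by 2.41, PAD4 by 3.47, SARD1 by 5.00, CBP60G by 6.07, FMO1 by 9.47 and ALD1 by 10.15, with an edgeR adjusted p of at most 2.05e-05. Of the 31 salicylic acid genes 29 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 4.57 (camera adjusted p = 5.18e-11; adjusted p = 0.0819 with an estimated correlation).

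Of the other defence lists in GBPL3-OX, 23 of 26 pattern-triggered immunity genes rose and 2 fell (median 3.03, camera adjusted p = 2.51e-07; adjusted p = 0.0819 with an estimated correlation), with FRK1 up by 8.27. For genes listed as intracellular immune receptors 23 of 26 rose and 1 fell (median 1.18, camera adjusted p = 6.38e-06, and adjusted p = 0.0819 with an estimated correlation). For cysteine-rich receptor-like kinases 25 of 34 rose and 4 fell (median 2.54 with the gene at 0 counts at its bound, 2.73 as fitted, camera adjusted p = 5.58e-05; adjusted p = 0.0874 with an estimated correlation). Camalexin and indole glucosinolate genes rose in 17 of 20 cases and fell in 2 (median 3.36, camera adjusted p = 4.86e-06; adjusted p = 0.138 with an estimated correlation), with CYP79B2 up by 5.56. Aliphatic glucosinolate genes fell in 17 of 18 cases (median -4.36 with the gene at 0 counts at its bound, -4.77 as fitted, camera adjusted p = 0.000135; adjusted p = 0.554 with an estimated correlation), MYB29 by 7.90. Jasmonate and ethylene genes rose in 24 of 29 cases and fell in 3 (median 2.57 with the genes at 0 counts at their bound, 2.74 as fitted, camera adjusted p = 6.48e-06; adjusted p = 0.221 with an estimated correlation). Glutathione transferases rose in 15 of 17 cases and fell in 1 (median 6.66 bounded, 6.74 as fitted, camera adjusted p = 6.38e-06; adjusted p = 0.205 with an estimated correlation). Wound and touch genes rose in 15 of 20 cases and fell in 2 (median 3.59, camera adjusted p = 0.000110; adjusted p = 0.0858 with an estimated correlation).

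Folding genes of the endoplasmic reticulum rose in 18 of 18 cases in GBPL3-OX (median 3.01, camera adjusted p = 7.63e-08; adjusted p = 0.156 with an estimated correlation), BIP2 by 4.15. Heat shock genes rose in 15 of 16 cases (median 2.41 bounded, 2.80 as fitted, camera adjusted p = 7.50e-05; adjusted p = 0.255 with an estimated correlation), and senescence genes in 14 of 14 (median 4.03 bounded, 5.78 as fitted, camera adjusted p = 3.47e-06; adjusted p = 0.169 with an estimated correlation). Photosynthesis genes fell in 45 of 45 cases (median -3.31, camera adjusted p = 7.54e-13; adjusted p = 0.480 with an estimated correlation), PSAE1 by 2.76. Cell wall expansion genes fell in 14 of 15 cases and rose in 1 (median -4.93 bounded, -6.47 as fitted, camera adjusted p = 7.50e-05; adjusted p = 0.0866 with an estimated correlation), and EXPA1 stood at -4.93. The lists of abscisic acid and cold (8 up and 14 down of 25, median -0.66), clock (2 up and 9 down of 15, -0.66), anthocyanin (2 up and 4 down of 7, -0.86), nuclear lamina, basket and Mediator (7 up and 2 down of 16, 0.22), stomatal (1 up and 3 down of 6, -1.20) and phloem genes (3 up and 1 down of 7, 0.04) were not called by camera, with adjusted p from 0.112 to 0.648. AG fell by 3.45 (edgeR adjusted p = 0.000935), again from 0.628 ± 0.0152 CPM. Apart from the salicylic acid list, the counts adjusted over the list alone were those given here.

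Against 0 counts in wild type, ATGLR1.2 was at least 214-fold higher in GBPL3-OX, GSTL1 at least 153-fold, AT1G76470 at least 116-fold, WAKL10 at least 104-fold, AT1G33030 at least 102-fold, AT1G57650 at least 92.1-fold, GLYI7 at least 83.4-fold and MYB122, a regulator of indole glucosinolates, at least 72.7-fold. Against 0 counts in GBPL3-OX, the auxin-responsive genes AT1G29430, SAUR29, SAUR68 and SAUR22 were at least 116-fold, 113-fold, 74.9-fold and 64.2-fold lower, with the reserve that members of this family can share reads. AT1G67750 was at least 74.2-fold lower, the kinase-like gene AT1G66940 at least 69.7-fold and the cell wall enzyme gene XTH8 at least 62.3-fold. XTH31 had 2 counts in GBPL3-OX against 2006 in wild type, a ratio with a 95% counting interval from 5.63e-05 to 0.00168. In all 6597 genes were higher and 6897 lower by edgeR, 4383 and 5180 of them by at least 2-fold. Higher genes made up 48.9% of the calls with TMM and 62.5% with library size alone, which moved the median of all genes to 0.43.

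The comparison of gbpl3-5 with wild type found leaves that differed in few genes. MAML-4, annotated as a methylthioalkylmalate synthase-like gene, fell by 3.50 on the log2 scale, from 19.98 ± 1.85 to 1.78 ± 0.353 CPM (SD, n = 2, SE 0.18, edgeR adjusted p = 1.77e-08). AT1G75945 was at least 21.9-fold higher, at 4.87 ± 0.972 CPM against 0 counts in wild type. The cyclophilin gene AT3G55920 rose by 2.96 (edgeR adjusted p = 0.000854; 2.51 and 0.0623 without wild type replicate 1, 3.70 and 0.0131 without wild type replicate 2) and the MADS-box gene AGL19 by 2.43 (0.00826, but 0.101 to 0.275 on leaving out each of the 4 libraries, with folds of 2.22 to 2.69). AT3G22235 fell by 1.19, AT1G27350, which encodes a RAMP4 protein of the secretory pathway, by 1.17, the defence-related gene LURP1 by 0.84 and the stomatal transporter gene ABCG22 by 0.70. Only 6 genes were higher and 8 lower by edgeR, with 963 at an unadjusted p under 0.05 and 4 higher and 10 lower by DESeq2.

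Also called in gbpl3-5, and named after their values were seen because their mean CPM was under the limit set for naming, were AT3G21950 (at least 19.7-fold higher), BBX31 (at least 6.14-fold), AT3G05170 (at least 4.60-fold) and the peroxisomal thiolase gene PKT4, which fell by 2.59 (edgeR adjusted p = 0.000173). ATCG00950 and ATCG01180, near-identical chloroplast ribosomal RNA copies that can share reads, fell by 0.94 and 0.93 and are uncertain. The call of ATCG00950 was lost with the replicate block, library size alone and limma-voom (adjusted p from 0.0560 to 0.0939) and on leaving out each of the 4 libraries in turn (0.0534 to 1), and that of ATCG01180 on leaving out 3 of them in turn (0.114 to 0.519). The calls of AT3G22235, AT1G27350, LURP1 and ABCG22 were each lost without at least 1 library (edgeR adjusted p from 0.0535 to 0.616), while their folds stayed near those of all libraries, at -1.18 and -1 for AT3G22235, -1.11 to -1.19 for AT1G27350, -0.76 to -0.91 for LURP1 and -0.68 to -0.72 for ABCG22 where the call was lost. With the replicate block LURP1 and ABCG22 were not called either (edgeR adjusted p = 0.0628 for both), nor was ABCG22 with library size alone (0.0936) or AGL19 by limma-voom (adjusted p = 0.0668). Without wild type replicate 1 only 4 genes were called, and 9, 7 and 6 without wild type replicate 2, gbpl3-5 replicate 1 and gbpl3-5 replicate 2.

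The 10 defence genes fixed for naming beforehand did not pass the test in gbpl3-5, unlike LURP1. PR1 stood at 3.63 ± 0.268 CPM (log2 fold change -0.35), ICS1 at 11.9 ± 0.115 (0.17) and ALD1 at 0.628 ± 0.193 (0.41). The values of PR2, PR5, EDS1, PAD4, SARD1, CBP60G and FMO1 were 0.11, 0.18, -0.31, -0.12, -0.39, -0.02 and -0.41, and the edgeR adjusted p of these 10 genes ran from 0.885 to 1. In each of the 20 lists 0 genes were called by edgeR, also when adjusted over the list alone. The salicylic acid list had a median of -0.02 (camera adjusted p = 0.0937), which turned to 0.02 with library size scaling and to 0.04 without wild type replicate 1. It passed the test without gbpl3-5 replicate 2, at -0.09 (camera adjusted p = 0.0128). Photosynthesis genes had a median of 0.00 and a mean of 0.01 (camera adjusted p = 0.792). The aliphatic glucosinolate list was called by camera, with a median of -0.20 and single genes from -0.93 to -0.08 (camera adjusted p = 0.0302; adjusted p = 0.702 with an estimated correlation). The medians of the other lists ran from -0.13 for clock genes to 0.06 for stomatal genes, with a camera adjusted p from 0.0866 to 0.921. Median and mean differed in sign for senescence (-0.08 and 0.22), nuclear (0.01 and -0.03) and phloem genes (-0.02 and 0.05). In simulated data for this comparison 76.4% of genes changed by 1 on the log2 scale were recovered, and 25.6% of those changed by 0.5. The changed genes there averaged above about 1 CPM, so these rates do not cover weaker genes such as GBPL1.

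The direct comparison of gbpl3-5 with GBPL3-OX contrasted the lines labelled as mutant and overexpressor of the same gene, whose GBPL3 counts did not differ (log2 fold change 0.17, 95% interval -0.17 to 0.51, edgeR adjusted p = 0.350). Salicylic acid genes were lower and photosynthesis and cell wall genes higher in gbpl3-5 by camera, and 0 of these 3 calls held with an estimated correlation. Of 31 salicylic acid genes 29 were lower and 1 higher (median -4.62, camera adjusted p = 4.58e-11; adjusted p = 0.0755 with an estimated correlation), and 45 of 45 photosynthesis genes were higher (median 3.40, camera adjusted p = 1.11e-12; adjusted p = 0.389 with an estimated correlation). Of 15 cell wall expansion genes 14 were higher and 1 lower (median 5.01 bounded, 6.30 as fitted, camera adjusted p = 8.41e-05; adjusted p = 0.0755 with an estimated correlation). Against 0 counts in GBPL3-OX, AT1G29430 was at least 125-fold higher, SAUR29 at least 112-fold and SAUR68 at least 83.9-fold, and the ratio for XTH31 had a 95% counting interval from 578 to 17280. The glycosyl hydrolase gene AT4G16260 was at least 198-fold lower in gbpl3-5, GSTU11 at least 167-fold, WAKL10 at least 136-fold and GLYI7 at least 110-fold. In all 7057 genes were higher and 6695 lower, and the share of higher genes was 51.3% with TMM and 39.0% with library size alone.

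The comparison of gbpl1-1 with gbpl3-5 gave a like contrast between lines labelled as mutants of different family members. AT4G16260 was at least 248-fold higher in gbpl1-1, GSTU11 at least 172-fold, WAKL10 at least 147-fold and GLYI7 at least 131-fold, against 0 counts in gbpl3-5. PDLP3 was at least 84.6-fold lower, EXPA3 at least 66.2-fold, AT2G38995 at least 64.0-fold and THI2.2 at least 62.7-fold. By edgeR 6615 genes were higher and 6917 lower, and the share of higher genes was 48.9% with TMM and 57.6% with library size alone.

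The comparison of gbpl1-1 with GBPL3-OX found few genes apart. MAML-4 was higher in gbpl1-1, at 26.5 ± 2.08 CPM against 1.42 ± 0.122 (SD, n = 2), a log2 fold change of 4.22 (SE 0.16, edgeR adjusted p = 2.00e-10). AT1G27350 was higher by 2.80, at 72.4 ± 10.1 against 10.4 ± 0.602 CPM, and AT3G55920 and AT3G55890 by 1.46 and 1.29. AT1G75945 had 0 counts in gbpl1-1 and was at least 16.7-fold lower there, AGL19 had a log2 fold change of -2.63, LHCB2.3 of -1.32 and the cap-binding gene ABH1 of -0.85. The remaining called genes, named after their values were seen, were PKT4 and MAF5, higher in gbpl1-1, and AT3G05170 and AT3G55910, lower. AT3G55890, AT3G55910 and AT3G55920 lie close together on chromosome 3, and the last 2 overlap, so without a stated strand their reads cannot be told apart in the overlap. In all 6 genes were higher and 6 lower by edgeR, with 966 at an unadjusted p under 0.05. Log2 CPM values correlated at 0.982 between the 2 gbpl1-1 libraries, and at 0.99 between gbpl1-1 replicate 1 and GBPL3-OX replicate 2. By this measure gbpl1-1 replicate 1 lay closer to that library than to its own replicate. The calls of LHCB2.3, AT3G55920, AT3G55890 and ABH1 were lost without at least 1 library, the first without gbpl1-1 replicate 2 or GBPL3-OX replicate 1 and the others without a GBPL3-OX library (edgeR adjusted p from 0.0641 to 0.331). All 4 were also lost in a fit of only the 4 libraries compared (edgeR adjusted p from 0.159 to 0.449), and that of ABH1 with the replicate block (0.0540). Where the call was lost, the log2 fold change was -1.15 to -1.34 for LHCB2.3, 1.24 and 1.45 for AT3G55920, 1.03 and 1.27 for AT3G55890 and -0.85 to -0.90 for ABH1. The total was 936 without gbpl1-1 replicate 1, 104 without gbpl1-1 replicate 2, 6 without GBPL3-OX replicate 1 and 8 without GBPL3-OX replicate 2.

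Gene lists shifted little between gbpl1-1 and GBPL3-OX. Camera called 9 of the 20 lists, and 0 of these calls held with an estimated correlation. By edgeR 1 of 45 photosynthesis genes was called, lower in gbpl1-1, and none in the other lists called by camera. Adjusted over each list alone, 1 or 2 genes passed in each list lower in gbpl1-1, and none in the higher ones. Lower in gbpl1-1 were the photosynthesis list, with a median of -0.21 (camera adjusted p = 1.27e-08; adjusted p = 0.484 with an estimated correlation), the endoplasmic reticulum list, also at -0.21 (camera adjusted p = 7.06e-05; adjusted p = 0.219 with an estimated correlation), and the phloem list at -0.26 (camera adjusted p = 4.75e-05; adjusted p = 0.0755 with an estimated correlation). So were the stomatal list at -0.47 (camera adjusted p = 0.0157; adjusted p = 0.219 with an estimated correlation) and the nuclear lamina, basket and Mediator list at -0.07 (camera adjusted p = 0.0146; adjusted p = 0.163 with an estimated correlation). Higher were the jasmonate and ethylene list at 0.10 (camera adjusted p = 0.00348; adjusted p = 0.384 with an estimated correlation) and glutathione transferases at 0.22 (camera adjusted p = 0.0146; adjusted p = 0.406 with an estimated correlation). The wound and touch list was also called higher by camera, at 0.12 (camera adjusted p = 0.0251, and adjusted p = 0.163 with an estimated correlation). So was the camalexin and indole glucosinolate list, at 0.07 (camera adjusted p = 0.0278, and adjusted p = 0.366 with an estimated correlation). The salicylic acid list was not called, at 0.07 (camera adjusted p = 0.101). The median of all genes was 0.009 with TMM and -0.123 with library size alone. The direction of list medians this close to 0 may therefore depend on the scaling, and they were not recomputed with library size alone. Of all tested genes, 90.14% had fold changes under 0.5 in size on the log2 scale. A call missing here does not show that a gene is equal in both lines.

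**Figure D3:**
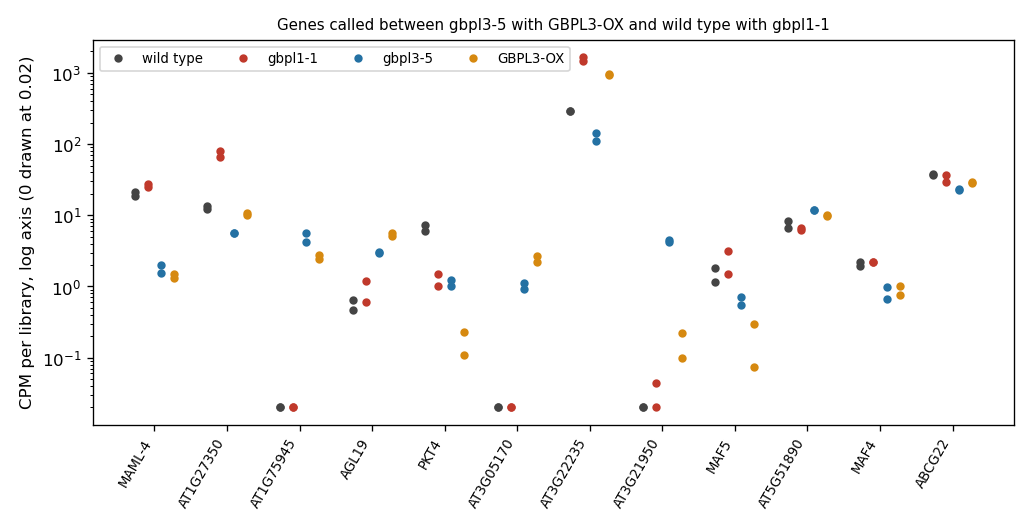
CPM on a log axis (points are single libraries, 0 counts drawn at the lower edge) of the 12 genes called in a contrast added after the data were seen, gbpl3-5 with GBPL3-OX against wild type with gbpl1-1. MAML-4 lay at 19.98 and 26.5 CPM on average in wild type and gbpl1-1, and at 1.78 and 1.42 in gbpl3-5 and GBPL3-OX.

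The changes from wild type in gbpl1-1 and GBPL3-OX were set against each other gene by gene. They shared 6272 higher genes and 6450 lower genes, where independent lists would share 2449 and 2648, and 2 genes were called in opposite directions. Across 17602 genes the fold changes correlated at 0.986, and 95.7% had the same sign. Both comparisons use the same wild type libraries. Simulations with all 8 libraries drawn anew from the wild type means gave a correlation of 0.594 and the same sign for 69.6% of genes. Shared calls averaged 0.150. These simulations hold the effect of sharing controls, but not the actual deviations of the 2 wild type libraries. The covariance was 6.64 against 0.0381 in the simulations, a difference of 6.60. Each part of a split of the 2 wild type libraries would hold 1, so the controls were not split, and part of the excess may come from them. The comparisons of gbpl1-1 with wild type and GBPL3-OX with gbpl3-5, which share no library and were paired after the data were seen, correlated at 0.970. This argues against shared controls as the main source of the excess. For gbpl1-1 with gbpl3-5 the correlation was 0.0890 and the covariance 0.117 (simulated 0.558 and 0.0381), with 1 higher and 3 lower genes shared, where independent lists would share 2.23 and 3.07, and 4 called in opposite directions. For gbpl3-5 with GBPL3-OX the correlation was 0.107 and the covariance 0.138 (simulated 0.586 and 0.0382). They shared 5 higher and 5 lower genes, where independent lists would share 2.25 and 3.13, and 2 were called in opposite directions. The simulated correlations are no yardstick for the pairs with gbpl3-5, since every simulated group was unchanged. Fold changes had an SD of 2.61 in gbpl1-1 and 2.58 in GBPL3-OX, against 0.50 in gbpl3-5.

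**Figure D4:**
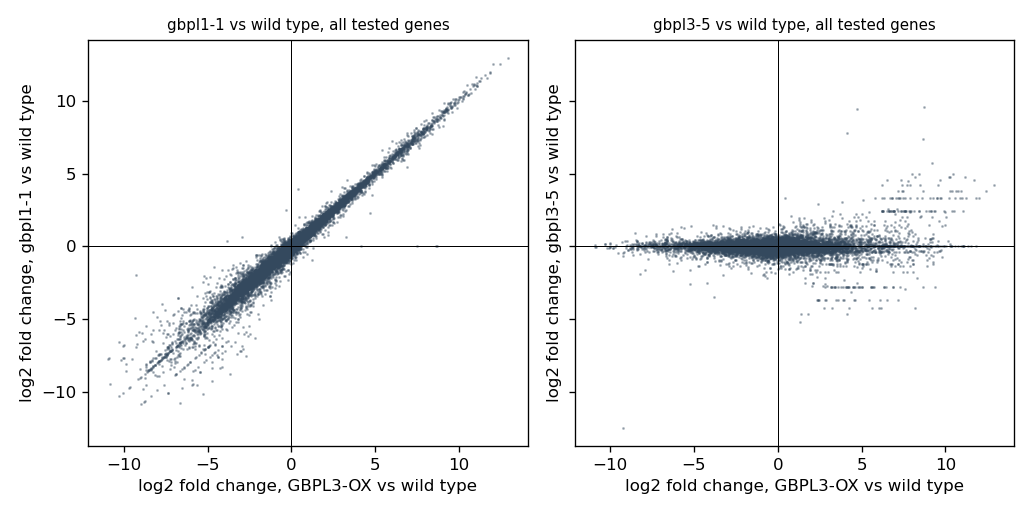
Log2 fold change against wild type of each tested gene in GBPL3-OX (x axis) and in gbpl1-1 (left, y axis) or gbpl3-5 (right, y axis), with a point for each of 17602 genes. The correlation was 0.986 on the left and 0.107 on the right, where all panels share the wild type libraries.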

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

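All tests of explanations in this part were chosen only after the results they bear on had been seen.

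Tests of the difference between lines gave 13752 genes whose change from wild type differed between gbpl3-5 and GBPL3-OX, 13532 between gbpl1-1 and gbpl3-5, and 12 between gbpl1-1 and GBPL3-OX. The share of reads outside annotated features, which no comparison used, averaged 3.32% in gbpl3-5 and 3.18% in wild type, above both wild type libraries. It averaged 2.21% in gbpl1-1 and 2.172% in GBPL3-OX, below both. Of 15 checks for a share above both wild type libraries chance alone gives 2.50 (16.7% each), and as many for a share below, where reads without a unique alignment in gbpl1-1 also lay, at 9.10% against 12.2% in wild type.

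GBPL3 counts were not raised in the libraries labelled GBPL3-OX. Too little depth is argued against, as the upper 95% limit of the log2 fold change was 0.37, below a 2-fold rise. An exchange of labels within the series is argued against for a line with at least a 2-fold rise, since over the 6 pairs of genotypes the largest limit in size was 0.78. A change of GBPL3 outside the counted transcript, or plants of another line, could also give the observed value of 0.01, and cannot be told apart with these counts.

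The libraries of gbpl1-1 and GBPL3-OX lay far from wild type and close to each other. Organelle genes taking most counts are argued against as the cause, since a change of their share moves all nuclear genes of a library by 1 factor, of at most 0.28 on the log2 scale here, while at least 4574 of 17424 nuclear genes lay beyond that shift by more than 2 SE in each direction, in both lines and with TMM or library size alone. So is a single library under both labels, as the closest gbpl1-1 and GBPL3-OX pair differed with a chi-square of 7.90 per degree of freedom. That value lay within the 3.18 to 10.96 between libraries of the same genotype. The 10.96 was between the 2 gbpl1-1 libraries, and the 7.90 between gbpl1-1 replicate 1 and GBPL3-OX replicate 2. Plants grown, handled or infected differently in the 2 sets may also raise defence and wound genes, and the wound and touch list had a median log2 fold change of 3.64 in gbpl1-1, which cannot be told apart from an effect of genotype because the sets follow the labels. An effect of both genotypes on immunity stays open in the same way and was not tested separately.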

How the results depend on the processing

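The counts of called genes in gbpl1-1 and GBPL3-OX against wild type, and of gbpl3-5 against either, stayed within 1.5 times the reported counts under each alternative tried. Leaving out a library gave 6094 to 6512 higher and 6277 to 6680 lower genes in gbpl1-1, and 6118 to 6386 and 6237 to 6516 in GBPL3-OX. The small counts moved, with the lone library assumed to vary like the other groups. In gbpl3-5, no low-count filter gave 26 higher and 40 lower genes, a fit of only the 4 libraries 12 and 22, and leaving out a library 2 to 4 and 2 to 5. Between gbpl1-1 and GBPL3-OX the filter setting gave 54 genes, the 4 libraries 5, and leaving out a library 6 to 936. The cause was not tested. The stricter filter removed GBPL1, which left 0 of the targeted genes called against 2. With an estimated correlation 0 of the 29 list calls held, the salicylic acid medians staying at 4.69 and 4.57 (adjusted p = 0.0819). Fry called 39 of the 60 list tests. It asks whether a list changes, not whether it changes more than other genes. By edgeR 75.51% of tested genes were called in gbpl1-1 and 76.66% in GBPL3-OX. Fry also called lists there that camera did not, such as clock genes in gbpl1-1 (fry adjusted p = 0.00121). A fry call in these lines thus does not set a list apart from other genes. For a change in 1 direction, the salicylic acid list had a fry adjusted p of 1.04e-06 in gbpl1-1 and in GBPL3-OX. In gbpl3-5 it was 0.273. For changes in either direction, fry gave this list an adjusted p of 0.00134 in gbpl3-5, with 0 of its genes called by edgeR.

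Of the named genes, and the lists against wild type, that passed their test, 0 turned direction. For lists, fry and the estimated correlation use the same fold changes, so these settings could not turn a median. Apart from salicylic acid, list medians were recomputed only with the replicate block, the other scalings and organelle genes left out. Lists compared between lines were not refitted under the alternatives. Among values that passed no test, the salicylic acid list in gbpl3-5 ran from -0.14 to 0.04 without a library, stood at 0.02 with library size alone, and passed at -0.09 without gbpl3-5 replicate 2. GBPL3 in gbpl1-1 turned to 0.11 with library size alone and ran from -0.48 (called, without wild type replicate 1) to 0.09 without a library. It ran from -0.07 to 0.50 in gbpl3-5 and from -0.23 to 0.34 in GBPL3-OX, where it was -0.02 with the stricter filter and -0.03 without GBPL3-OX replicate 1. In gbpl3-5, PR2 ran from -0.06 to 0.32 and PR5 from -0.07 to 0.51 (-0.04 without gbpl3-5 replicate 2). CBP60G there turned to 0.02 with library size alone, 0.05 without wild type replicate 2 and 0.04 without gbpl3-5 replicate 1. The cause was not tested. The labels do not say that libraries with the same replicate number share a day or batch. Correlations of their deviations ran from -0.0650 to 0.0460, which does not exclude a batch that acts on few genes. With the replicate block 4 genes were higher and 5 lower in gbpl3-5, and 11 differed between gbpl1-1 and GBPL3-OX. Depth limits GBPL1, at 2 to 13 counts per library.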

Other observations

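Gene families chosen after the data were seen, as was every test in this part, extended the contrast between wild type and the lines gbpl1-1 and GBPL3-OX. In gbpl1-1, 42 of 50 tested WRKY transcription factors, many of which act in defence, rose and 2 fell, with a median log2 fold change of 3.05 with genes at 0 counts at their bound and 3.77 as fitted (camera adjusted p = 2.87e-09, and adjusted p = 0.0314 with an estimated correlation). In GBPL3-OX 41 rose and 3 fell (median 3.16 bounded, 3.69 as fitted; camera adjusted p = 2.87e-09, and adjusted p = 0.0314 with an estimated correlation). NAC transcription factors rose in 33 of 42 cases in gbpl1-1 and fell in 3 (median 1.93, camera adjusted p = 1.75e-07), and rose in 36 and fell in 1 in GBPL3-OX (median 2.37, camera adjusted p = 6.40e-08; adjusted p = 0.141 with an estimated correlation in both lines). All 26 tested proteasome subunits, which degrade tagged proteins, rose in gbpl1-1 (median 2.2, camera adjusted p = 5.36e-09) and in GBPL3-OX (median 2.26, camera adjusted p = 3.52e-09; adjusted p = 0.261 with an estimated correlation in both lines). Autophagy genes rose in 23 of 29 cases and fell in 1 in gbpl1-1 (median 1.1, camera adjusted p = 0.000153), and rose in 22 and fell in 1 in GBPL3-OX (median 1.09, camera adjusted p = 0.000162; adjusted p = 0.261 with an estimated correlation in both lines).

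By camera 4 families were lower in both lines, and 0 of these calls held with an estimated correlation. Aquaporins of the plasma membrane and vacuole fell in 15 of 16 cases in gbpl1-1 (median -3.03, camera adjusted p = 6.44e-06) and in 15 in GBPL3-OX (median -3.16, camera adjusted p = 6.41e-06; adjusted p = 0.261 with an estimated correlation in both lines). Tubulins fell in 11 of 14 cases and rose in 1 in either line (medians -2.45 and -2.35, camera adjusted p = 0.000766 and 0.000472; adjusted p = 0.261 with an estimated correlation). Aquaporins and tubulins have close paralogs that can share reads. Genes of the chloroplast genome fell in 106 of 119 cases in gbpl1-1 and 109 in GBPL3-OX (medians -1.02 and -0.92, camera adjusted p = 3.82e-12 in both; adjusted p = 0.324 with an estimated correlation), and the medians were -0.68 and -0.44 with library size alone. Nuclear genes annotated as ribosomal proteins fell in 141 of 261 cases and rose in 30 in gbpl1-1 (median -0.37, camera adjusted p = 0.000508; adjusted p = 0.564 with an estimated correlation), and fell in 172 and rose in 24 in GBPL3-OX (median -0.53, camera adjusted p = 4.83e-06; adjusted p = 0.439 with an estimated correlation). With library size alone these medians were close to 0, at -0.03 and -0.05, while the median of all genes moved to 0.30 and 0.43. Histone genes were not called in these 2 lines (medians -0.28 and -0.52, camera adjusted p = 0.210 and 0.0583), and their median in gbpl1-1 turned to 0.06 with library size alone. Genes of the mitochondrial genome were not called in these lines either (medians -0.01 and 0.04, camera adjusted p = 0.939 and 0.886), and in gbpl1-1 the median turned to 0.03 with DESeq2 size factors and 0.33 with library size alone.

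In gbpl3-5 camera called 3 of the 10 families, each with 0 genes called by edgeR. Mitochondrial genome genes had a median of -0.11 (59 genes, camera adjusted p = 0.00307; adjusted p = 0.227 with an estimated correlation). Nuclear ribosomal protein genes stood at 0.09 (261 genes, camera adjusted p = 0.00111; adjusted p = 0.578 with an estimated correlation) and histones at 0.13 (40 genes, camera adjusted p = 0.00650; adjusted p = 0.356 with an estimated correlation). The other 7 families were not called there, with a camera adjusted p from 0.0551 to 0.850.

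A contrast of 2 lines with 2 others was also tested. Contrasted with wild type and gbpl1-1, gbpl3-5 and GBPL3-OX together had 5 genes higher and 7 lower by edgeR (927 at an unadjusted p under 0.05). MAML-4 had a log2 fold change of -3.86, AT1G27350 of -1.99, PKT4 of -2.69 and AT3G22235 of -0.95. The flowering regulators MAF5 and MAF4, which are neighbours, stood at -2.43 and -1.33, AGL19 at 2.53, the peroxidase gene AT5G51890 at 0.62 and ABCG22 at -0.44. AT1G75945 and AT3G05170 had 0 counts in wild type and gbpl1-1. AT3G21950 had 1 count there. The contrast averages 2 lines, and only 6 of the 12 genes were called in its direction both in gbpl3-5 against wild type and in GBPL3-OX against gbpl1-1: MAML-4, AT1G27350, AT1G75945, AGL19, PKT4 and AT3G05170. Of the others, AT3G21950 stood at 4.38 CPM in gbpl3-5 and 0.159 in GBPL3-OX, and AT3G22235 at 954 CPM in GBPL3-OX against 289 in wild type. Within the 6, the pairing was not clean for PKT4 or AT1G27350. PKT4 averaged 1.25 CPM in gbpl1-1, near the 1.12 of gbpl3-5 and below the 6.74 of wild type. AT1G27350 averaged 10.4 CPM in GBPL3-OX, near the 12.8 of wild type and below the 72.4 of gbpl1-1. The other crossed pairing, gbpl1-1 with gbpl3-5, gave 2 genes higher and 3 lower, with 965 at an unadjusted p under 0.05. AT1G27350 was called there too, at 0.81 (edgeR adjusted p = 0.00245).

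Chance agreement is argued against for the 6 genes called in both. The comparisons of gbpl3-5 with wild type and of GBPL3-OX with gbpl1-1 share no library, yet 6 genes were called in the same direction in both, where independent lists would share 0.00477, and 1 was called in opposite directions. A candidate explanation is a background shared by the plants of gbpl3-5 and GBPL3-OX, such as stretches of genome that differ between the 2 pairs of lines. The 12 genes held 2 pairs within 1 Mb, against 1.26 on average for random genes (permutation p = 0.339). BBX31, AT3G21950 and AT3G22235, called in gbpl3-5 against wild type, start at 7708833, 7734219 and 7854419 on chromosome 3, and the 12 nuclear genes called there held 3 pairs within 1 Mb against 1.27 (permutation p = 0.125). Stretches that differ between the pairs of lines, or between gbpl3-5 and wild type, thus stay open, with too few genes to tell. Of comparisons without a shared library, gbpl1-1 with wild type and GBPL3-OX with gbpl3-5 correlated at 0.970 across genes. They shared 12474 calls in the same direction, with 4 opposite. Over the same genes, gbpl3-5 with wild type and GBPL3-OX with gbpl1-1 correlated at only 0.096, with the same sign for 49.0%.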
